A study of Homo sapiens with 20 samples.

How the data were processed

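RNA was measured in 20 libraries: 6 from U2OS cells with an FKBP tag on PDPK1, 8 from U2OS cells with an FKBP tag on WDR5, and 6 from a HEK293 clone with the R3A mutation in PDPK1. The FKBP tag is a small domain bound by dTAG47, which recruits a ubiquitin ligase to the tagged protein. Per the labels' protocols, RNA was taken from cells in Trizol, purified on columns, depleted of ribosomal RNA and sequenced at a company or a university core. Which library went to which site is not given in the sources used here. Per the submitters' processing notes, the authors aligned reads to hg19 with STAR, counted them per gene with featureCounts and used DESeq2. Tool versions, the annotation release, the strand setting and the handling of reads that match several genes are not given in the sources used here. The 3 deposited tables hold whole-number read counts per gene that the authors did not normalise, for 42475 (PDPK1 set), 45191 (WDR5 set) and 43617 (HEK293 set) genes, each with identifier, symbol, class and coordinates.

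Columns were tied to samples by their names. As written, the names of the 4 DMSO columns in the WDR5 table match labels of the WDR5 set. Once punctuation is dropped, all but DMSO 4 also match labels of the PDPK1 set. These columns were used as the 4 libraries of their group without a replicate number. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom of 2.06 to 20.1 over genes). Small structural and mitochondrially encoded RNA took 18.4 to 20.8% of counts in the PDPK1 set, 12.0 to 13.4% in the WDR5 set and 19.8 to 22.2% in HEK293. Total counts were lower in the 6 libraries of the PDPK1 set and in 5 of the 6 HEK293 libraries than in any library of the WDR5 set. The labels do not say whether libraries of a group came from separate cultures.

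Each table was fitted on its own with edgeR's quasi-likelihood test, with TMM factors, filterByExpr and Benjamini-Hochberg adjustment, and genes under an adjusted p of 0.05 were called. The 3 HEK293 groups shared 1 estimate of spread. The difference between the WDR5 and PDPK1 effects was tested in 1 model of the 14 U2OS libraries over the 39912 identifiers both tables hold. SEs of log2 fold changes were taken from the F statistic, as the absolute log2 fold change over its root. CPM values use the TMM factors. Overlaps of calls were tested with one-sided Fisher's exact tests, adjusted over 20 overlaps, and set beside the product of the list sizes over the genes tested in both. These tests take genes as independent, which they are not, so their p-values do not measure the spread between libraries. For the HEK293 comparisons that share WT, counts of all HEK293 libraries, WT included, were simulated 30 times with no difference between groups. The replicate numbers were not used in the fits. Tests, samples, gene lists and the rule for named genes were fixed before the data were examined.

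The 28 gene lists had at least 5 tested members each and were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether members move one way without reference to other genes. Members were matched among protein-coding entries (and structural RNA for that list), so a few members listed under another class, such as UHRF1, KMT2B and NEFL, were not counted. Genes in more than 1 list count in each: THBS1 in the YAP/TEAD and U2OS-type lists, TGFBI in the extracellular matrix and U2OS-type lists, SESN1 in the FOXO and p53 lists, and SESN2 in the ATF4 and p53 lists. The U2OS-type and HEK293-type lists hold marker genes of either line. Named genes were PDPK1 and WDR5. To these were added, per comparison, the 8 largest increases and 8 largest decreases among called genes with a mean of at least 5 CPM and no overlap between groups. From each list past its camera threshold, the 3 called members with the smallest p in the list's direction were named (4 for ribosomal protein and G2/M genes), and between comparisons the 6 with the smallest adjusted p per direction. Clone-based names, structural RNA and pseudogenes were passed over, and 2 genes that met the rule are not reported here. Other members were named where a list had 5 or fewer calls or members went against the list, and these, with the extra members given for some lists, were chosen after their values were seen.

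The A share and GC share of each gene's longest transcript came from GENCODE 29 on GRCh38, another build than the authors', and served only as gene properties. Length was the gene length in bases given with the authors' counts. Both shares were available for 96.2 to 96.5% of genes tested and 97.7 to 99.2% of those called. A high A share means one at or above the 90th percentile of the tested protein-coding genes above a minimum level (31.4 or 31.5% A). This division and an offset were added after the trend with A share had been seen. The offset, per gene and library, came from a smooth of log2 CPM on both shares and length (mgcv). The smooth was fitted on protein-coding genes above a minimum level, and values outside their range were set to its ends. For other classes, such as structural RNA, the offset extends that trend. Genes with near-identical copies share reads to an unknown extent. These are PDPK1 with PDPK2 (chromosome 16, 2666122 to 2693297, 0.141 CPM with the vector and 0.526 CPM with WT, edgeR adjusted p = 0.193), ribosomal protein genes with their pseudogenes, histone genes, and DPY19L2. The RPS9 entry named after PDPK1 degradation and the TXNIP entry named with the vector lie on alternate assembly sequences. Without a stated strand setting, reads of antisense or overlapping genes cannot be separated.

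The procedure was tested on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold. The changed genes were drawn from those of at least 1 CPM, so recovery below that level was not measured. It recovered 71 and 90% in the PDPK1 set (17812 genes), 87 and 99% in the WDR5 set (22029 genes), and 66 and 83% for the difference (22126 genes). In HEK293 it recovered 80 and 93% for R3A against WT (18072 genes), 80 and 91% for vector against WT (18051 genes) and 77 and 93% for R3A against vector (17947 genes). False calls were 6.29, 4.94, 4.35, 6.44, 8.64 and 6.38% of the calls in the same order. A shifted list was found in each of these 6 simulations, with 0 to 3 other lists past the threshold. A simulated composition trend gave 84 calls in the PDPK1 set, 5857 in the WDR5 set and 2057 for R3A against WT. The offset left 3, 6 and 9, but it is fitted on the same properties, so this removal was largely built in. The simulated trend was not scaled to the real libraries, so these counts do not show how many real calls composition gave. With the offset on the real counts, 759 of 960, 8506 of 9081 and 171 of 291 calls were kept in the same direction, in that order. Alternatives were DESeq2, limma-voom, DESeq2 and upper-quartile factors, no filter, a filter at 1 CPM, library sizes without structural and mitochondrial RNA, an adjusted p of 0.01, a 2-fold minimum, a replicate block, each library left out, HEK293 groups fitted in pairs, and the added offset. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and mgcv 1.9.3 were used.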

Results

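RNA was sequenced from 3 sets of engineered human cells. The first set was U2OS, an osteosarcoma line, with an FKBP degron tag on the endogenous kinase PDPK1. These cells received 0.01% DMSO or 500 nM dTAG47, a compound that directs FKBP-tagged proteins to degradation, for 24 h, with 3 libraries per condition. The second set was U2OS with the same kind of tag on WDR5, a scaffold protein of several chromatin complexes, under the same treatments with 4 libraries per condition. The third set was a clone of HEK293, an embryonic kidney line, that carries the R3A point mutation in PDPK1. It received retroviral wild-type PDPK1 (WT), an empty vector, or R3A PDPK1, with 2 libraries each. The WIN site is the pocket of WDR5 that binds arginine-containing motifs, and the series is about the proteins that bind there. The values are read counts per gene on hg19. Total counts per library were 19871371 to 21464546 with DMSO and 21116254 to 25133794 with dTAG47 in the PDPK1 set. They were 33938726 to 38739590 with DMSO and 31035320 to 37852780 with dTAG47 in the WDR5 set. In HEK293 they were 31381546 and 15636444 (WT), 20261267 and 23283177 (vector), and 27246049 and 23305211 (R3A). Levels below are mean ± SD in CPM, the counts scaled to a common library size, and log2 fold changes are ± SE. Labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

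The targeted genes were read first. In the HEK293 clone, PDPK1 (ENSG00000140992.14, chromosome 16, 2587965 to 2653189, protein coding) was at 35.1 ± 1.72 CPM with WT, 7.48 ± 0.414 CPM with the vector and 27.0 ± 2.11 CPM with R3A (n = 2 each). The order of these levels matches the labels, since the constructs add PDPK1 transcripts to those of the clone. R3A was below WT by a log2 fold change of -0.36 ± 0.07 (edgeR adjusted p = 0.00433), a call lost without R3A 2 (adjusted p = 0.178) and with DESeq2. In the degron cells the tag acts on protein, so mRNA levels do not check the depletion. No cells without a tag received dTAG47. Within either set, changes after degradation thus cannot be told apart from effects of the compound itself. PDPK1 mRNA was at 36.3 ± 1.06 CPM against 37.4 ± 3.53 CPM in the PDPK1 set (dTAG47 against DMSO, n = 3 each; edgeR adjusted p = 0.846). WDR5 (ENSG00000196363.5, chromosome 9, 137000487 to 137025093, protein coding) was at 101 ± 2.77 CPM against 105 ± 5.01 CPM in the WDR5 set (n = 4 each; edgeR adjusted p = 0.151). PDPK1 has a near-identical copy, PDPK2, and how reads matching both were counted is not stated, so its level is uncertain by that share.

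The first comparison asked what changes when PDPK1, a kinase that activates AKT and related kinases, is degraded for 24 h in U2OS. Of the G2/M and mitosis genes 22 of 42 fell, and of the sterol and fatty acid synthesis genes 8 of 28, while 5 of 25 lysosome, 6 of 25 extracellular matrix and 5 of 21 YAP/TEAD genes rose. These 5 lists passed camera's test, and none did with an estimated correlation (adjusted p = 0.177, 0.192, 0.177, 0.354 and 0.312 with an estimated correlation). CENPE, a kinesin of the kinetochore, was at 89.1 ± 8.69 CPM against 213 ± 36.6 CPM (dTAG47 against DMSO, n = 3 each; log2 fold change -1.26 ± 0.12, edgeR adjusted p = 0.000317). ITGA2 (ENSG00000164171.6, chromosome 5, 52285156 to 52390609, protein coding), a collagen-binding integrin subunit, rose to 165 ± 15.4 CPM against 70.5 ± 0.709 CPM (1.23 ± 0.09, adjusted p = 5.90e-05). In all, 960 of 18107 genes tested were called, 481 higher and 479 lower, of which 120 changed at least 2-fold.

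Among the G2/M and mitosis genes, 22 of 42 fell and 0 rose (0 rose and 33 fell when adjusted over the list alone; camera adjusted p = 1.12e-28, adjusted p = 0.177 with an estimated correlation). The members with the smallest p were CENPE, CENPF, ASPM and TTK, which act at kinetochores, at spindle poles and in the spindle checkpoint. CENPF fell to 479.9 ± 39.3 CPM against 962 ± 75.7 CPM, and ASPM to 147 ± 18.4 CPM against 309.7 ± 35.9 CPM. All 42 members had a negative log2 fold change, with a median of -0.36. Across 11629 protein-coding genes, log2 fold changes fell with the share of A in the transcript (Pearson r = -0.31, Spearman rho = -0.36, genes not being independent replicates), and the G2/M list moved with it. The 16 members with a high A share had a median of -0.56 and the other 26 a median of -0.26. Against the mean of the 6 libraries, log2 CPM per 10 percentage points of A share had slopes of 0.125 and 0.210 in DMSO 1 and 2, -0.0766 in DMSO 3, and -0.110 to -0.0611 with dTAG47. DMSO 3 thus lay on the side of the dTAG47 libraries in this property. Replication-dependent histones (7 of 42 fell, 0 rose; 0 rose and 9 fell when adjusted over the list alone; camera adjusted p = 1.62e-05, adjusted p = 0.509 with an estimated correlation) included HIST1H3C, HIST1H2AL and HIST1H1B, whose highest group mean was 7.09 CPM and whose reads can be shared with near-identical copies. In the DNA replication and G1/S list E2F2 fell, as the 1 call among 40 members (0 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.00208, adjusted p = 0.390 with an estimated correlation).

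Of the sterol and fatty acid synthesis genes, 8 of 28 fell, 14 with an offset for base composition and length, and 0 rose (0 rose and 17 fell when adjusted over the list alone; camera adjusted p = 9.58e-09, adjusted p = 0.192 with an estimated correlation). SCD, the stearoyl-CoA desaturase, fell to 316 ± 17.9 CPM against 425 ± 15.9 CPM, and IDI1 and SC5D, enzymes of the isoprenoid and cholesterol pathways, had log2 fold changes of -0.46 ± 0.10 and -0.44 ± 0.10. In the lysosome and autophagy list 5 of 25 rose and 0 fell (14 rose and 0 fell when adjusted over the list alone; camera adjusted p = 1.74e-08, adjusted p = 0.177 with an estimated correlation): CTSB, WIPI1, SQSTM1, HEXA and FLCN. The protease gene CTSB rose to 757 ± 51.5 CPM against 478 ± 37.0 CPM. FOXO targets FBXO32, a muscle ubiquitin ligase gene, and KLF6 rose, 2 of 23 (5 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.0129, adjusted p = 0.222 with an estimated correlation). FBXO32 was at 39.9 ± 5.14 CPM against 23.4 ± 2.22 CPM. In the ATF4 and amino acid response list 4 of 32 fell and 1, DDIT3, rose (2 rose and 6 fell when adjusted over the list alone; camera adjusted p = 0.0230, adjusted p = 0.369 with an estimated correlation). Those that fell were PSAT1 and PSPH of serine synthesis, the glycine transporter SLC6A9, and VLDLR. Heat shock genes HSP90AA1 and HSPH1 fell, 2 of 16 (0 rose and 4 fell when adjusted over the list alone; camera adjusted p = 0.00302, adjusted p = 0.354 with an estimated correlation).

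Extracellular matrix genes rose in 6 of 25 with 0 falling (7 rose and 0 fell when adjusted over the list alone; camera adjusted p = 4.02e-06, adjusted p = 0.354 with an estimated correlation), led by COL4A1 at 361 ± 7.08 CPM against 229 ± 10.7 CPM, LAMB1 and TIMP1. YAP/TEAD targets rose in 5 of 21, among them THBS1, GADD45B, CTGF and CYR61 (6 rose and 0 fell when adjusted over the list alone; camera adjusted p = 1.62e-05, adjusted p = 0.312 with an estimated correlation). THBS1, the matrix glycoprotein thrombospondin, was at 1725 ± 154 CPM against 1139 ± 115 CPM. Immediate early and MAPK feedback genes rose in 6 of 25, with DUSP1, EGR2 and ETV4 first (8 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.00180, adjusted p = 0.354 with an estimated correlation). With the offset 3 of these list members rose and 1 fell. Interferon-stimulated genes split: IFIT2, IFIT3, IFI44, OASL and DDX60 rose while SAMD9 and SAMD9L fell, of 30 tested (6 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.0160, adjusted p = 0.312 with an estimated correlation). With an offset for base composition and length, 6 members rose and 0 fell. IFIT2 was at 19.5 ± 3.97 CPM against 7.96 ± 0.554 CPM. RELB and NFKB1 rose among 13 NF-kB and cytokine genes (3 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.0250, adjusted p = 0.289 with an estimated correlation). Markers of the U2OS type, CD44 and THBS1, rose, 2 of 10 (5 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.000831, adjusted p = 0.177 with an estimated correlation).

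Cytosolic ribosomal protein genes rose in 4 of 82 (RPLP2, RPL39, RPL22L1 and an RPS9 entry on an alternate assembly sequence; 0 rose and 0 fell when adjusted over the list alone; camera adjusted p = 1.08e-06, adjusted p = 0.562 with an estimated correlation). The p53 target list had 0 genes called and a median of 0.13 (0 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.0129, adjusted p = 0.376 with an estimated correlation). Small structural RNAs rose in 8 of 166 (9 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.000680, adjusted p = 0.354 with an estimated correlation; 0.0749 with the offset), and structural and mitochondrial RNA took 18.4 to 19.0% of counts with DMSO and 19.4 to 20.8% with dTAG47. Lists that missed the camera threshold were mitochondrial ribosomal proteins (1 rose), translation factors (EIF5B fell), ribosome biogenesis (0 called), components of the PI3K-PDPK1-AKT-mTOR pathway (PIK3R1 fell), WDR5-containing complexes (0), HOX genes (0), glycolysis and hypoxia (NDRG1 rose), oxidative phosphorylation (0), unfolded protein response (HERPUD1 rose), HEK293-type markers (LIN28B fell) and mitochondrially encoded mRNAs (0). Their camera adjusted p-values ran from 0.176 to 0.997.

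Among called genes with a mean of at least 5 CPM and no overlap between groups, the largest increases were in ESM1 (10.2 ± 0.559 CPM against 3.60 ± 0.622 CPM), CTHRC1 (log2 fold change 1.46 ± 0.16), IFIT2, F13A1 (1.26 ± 0.13), ITGA2, KISS1, DGKI and SCG5. ESM1 and CTHRC1 encode secreted proteins and F13A1 a subunit of coagulation factor XIII. The largest decreases were in RNF43 (-1.41 ± 0.10), IGSF10, CENPE, SOX2 (-1.25 ± 0.13), EPHA5, ZNF480, BRCA2 (-1.12 ± 0.13) and ASPM. RNF43 is a ubiquitin ligase for Wnt receptors, SOX2 a transcription factor and BRCA2 a homologous recombination protein. The count of calls depended on single libraries: it was 1848 without DMSO 3, 295 without DMSO 2, and 451, 440 and 458 without dTAG47 1, 2 and 3. Of 56 named genes called, 25 lost their call without at least 1 library, among them the named sterol, heat shock, ATF4, NF-kB and ribosomal protein genes. SCD reached adjusted p = 0.0784 and IDI1 0.105, and none of the 16 largest changes was among these 25.

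The WDR5 degron comparison asked what changes when WDR5 is degraded for 24 h. Of 86 cytosolic ribosomal protein genes 45 fell and 34 rose, 25 of 28 p53 targets and all 43 G2/M genes rose, and 19 of 33 HOX genes fell and 2 rose. With an estimated correlation the p53 and G2/M lists passed, and the ribosomal protein and HOX lists did not (adjusted p = 0.113 and 0.223 with an estimated correlation). RPL34 (ENSG00000109475.12, chromosome 4, 109541722 to 109551568, protein coding), of the large ribosomal subunit, fell to 119.6 ± 3.62 CPM against 202 ± 3.30 CPM (dTAG47 against DMSO, n = 4 each; log2 fold change -0.76 ± 0.03, edgeR adjusted p = 1.99e-15). CDKN1A (ENSG00000124762.9, chromosome 6, 36644305 to 36655116, protein coding), the p21 cell cycle inhibitor, rose to 226 ± 0.388 CPM against 156 ± 1.92 CPM (0.54 ± 0.03, adjusted p = 4.93e-14). Calls numbered 9081 of 22419 genes, 4383 higher and 4698 lower (5469 and 4477 with an offset for base composition and length), with a median absolute log2 fold change of 0.27, and 413 of them changed at least 2-fold, 52 up and 361 down.

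Of 86 cytosolic ribosomal protein genes, 45 fell, 34 rose and 7 did not pass (34 rose and 45 fell when adjusted over the list alone; camera adjusted p = 1.57e-22, adjusted p = 0.113 with an estimated correlation). Among large-subunit genes 33 fell, 14 rose and 5 did not pass, and among small-subunit genes 12 fell, 18 rose and 2 did not pass. RPL23, RPL34, RPL6 and RPL5 had the smallest p, with RPL23 at 316 ± 2.71 CPM against 508 ± 8.58 CPM. RPLP0 was at the other end with a log2 fold change of 0.32 ± 0.03. Ribosomal protein genes have many processed pseudogenes, so reads may be shared where the counting allowed it. Ribosome biogenesis genes fell in 24 of 40, UTP20 to 48.7 ± 0.881 CPM against 75.7 ± 0.878 CPM, and NOP56, FBL and NPM1 rose (3 rose and 24 fell when adjusted over the list alone; camera adjusted p = 7.66e-06, adjusted p = 0.181 with an estimated correlation). Mitochondrial ribosomal proteins fell in 37 and rose in 10 of 75, with MRPL45, MRPS15 and MRPS27 first (12 rose and 39 fell when adjusted over the list alone; camera adjusted p = 0.00361, adjusted p = 0.283 with an estimated correlation). Translation factors rose in 13 and fell in 9 of 35, with EIF1, EIF4G2 and EEF1D first among those that rose (13 rose and 9 fell when adjusted over the list alone; camera adjusted p = 0.0422, adjusted p = 0.457 with an estimated correlation).

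**Figure D1:**
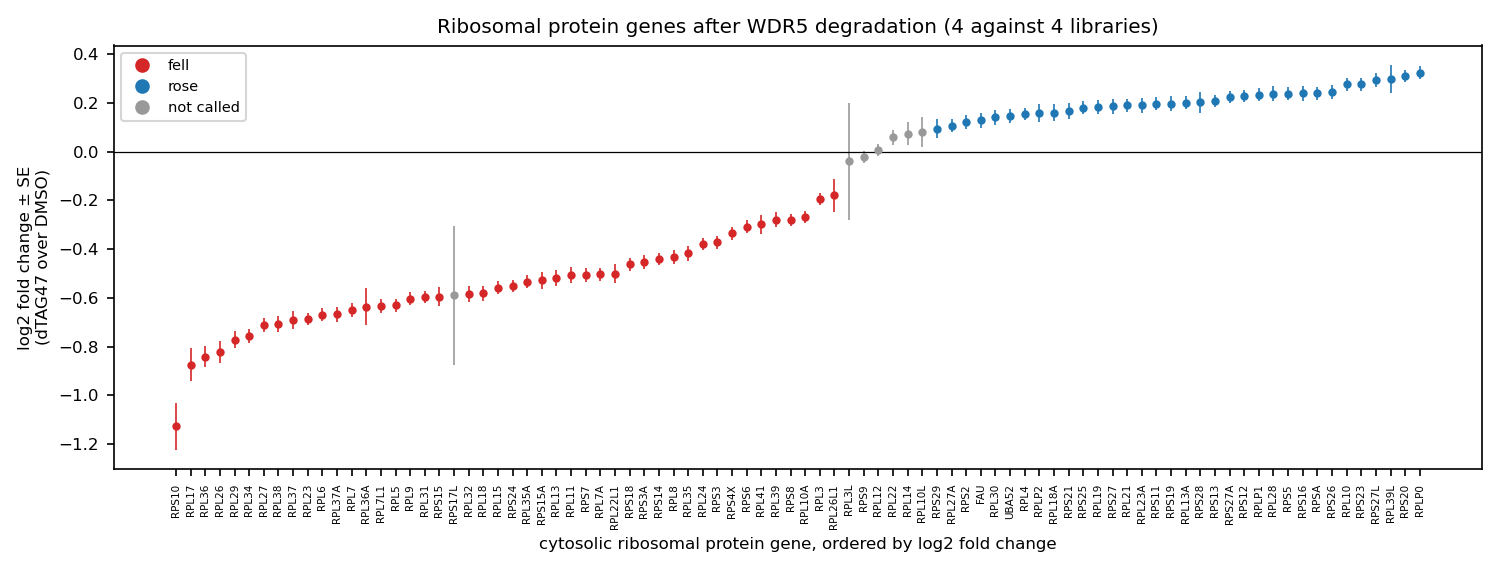
Log2 fold change (dTAG47 over DMSO, points) with its SE (bars) of each tested cytosolic ribosomal protein gene after WDR5 degradation, in order of size, from 4 against 4 libraries. Red points fell, blue points rose and grey points did not pass, with 45, 34 and 7 genes in these classes.

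p53 targets rose in 25 of 28 and 1, CMBL, fell (25 rose and 1 fell when adjusted over the list alone; camera adjusted p = 1.68e-36, adjusted p = 0.00218 with an estimated correlation). BTG2, an antiproliferative gene, was at 70.7 ± 1.26 CPM against 42.2 ± 0.789 CPM, and TP53INP1 at 59.6 ± 3.33 CPM against 32.4 ± 1.44 CPM. All 43 G2/M and mitosis genes rose (43 rose and 0 fell when adjusted over the list alone; camera adjusted p = 8.67e-35, adjusted p = 0.0313 with an estimated correlation), with a median log2 fold change of 0.25. KIF20A, a mitotic kinesin, was at 205 ± 4.21 CPM against 146 ± 1.95 CPM, and HMMR, PSRC1 and CKAP2 followed. The trend of fold changes with the A share was weaker in these libraries (Pearson r = 0.07 over 12126 genes), and G2/M members with a high A share and the others had medians of 0.24 and 0.28. Replication-dependent histones rose in 33 of 51 and 0 fell (34 rose and 0 fell when adjusted over the list alone; camera adjusted p = 3.92e-08, adjusted p = 0.285 with an estimated correlation). HIST1H2BN reached 174 ± 8.73 CPM against 133 ± 3.97 CPM, while HIST1H3C and HIST1H2BB rose from 0.381 and 0.416 CPM with DMSO to 2.22 and 2.39 CPM. FOXO targets rose in 13 of 23, with SESN3, CCNG2 and SESN1 first, and INSR, RBL2 and ERBB3 fell (13 rose and 4 fell when adjusted over the list alone; camera adjusted p = 0.000607, adjusted p = 0.0512 with an estimated correlation).

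In the glycolysis and hypoxia list 23 of 30 rose and 1, ENO2, fell (24 rose and 2 fell when adjusted over the list alone; camera adjusted p = 8.44e-11, adjusted p = 0.0768 with an estimated correlation), with NDRG1 at 149 ± 4.09 CPM against 98.7 ± 4.22 CPM ahead of TPI1 and ALDOA. ATF4 and amino acid response genes rose in 22 of 34 and ATF3 fell (22 rose and 1 fell when adjusted over the list alone; camera adjusted p = 3.63e-08, adjusted p = 0.197 with an estimated correlation), with PHGDH, PCK2 and SESN2 first. Oxidative phosphorylation genes such as ATP5B, COX8A and SDHA rose in 26 and fell in 5 of 74 (26 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.00862, adjusted p = 0.341 with an estimated correlation). Lysosome and autophagy genes rose in 14, with NEU1, SQSTM1 and MAP1LC3B first, and fell in 8 of 27 (15 rose and 9 fell when adjusted over the list alone; camera adjusted p = 0.0275, adjusted p = 0.140 with an estimated correlation). Unfolded protein response genes such as CALR, HSP90B1 and HYOU1 rose in 12 of 18, and SDF2L1, SEL1L and DNAJB11 fell (12 rose and 4 fell when adjusted over the list alone; camera adjusted p = 0.0275, adjusted p = 0.199 with an estimated correlation). Mitochondrially encoded mRNAs rose in 7 of 13, MT-CO2, MT-ND2 and MT-ND1 first (8 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.0275, adjusted p = 0.513 with an estimated correlation).

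HOX genes fell in 19 of 33 and 2 rose (3 rose and 20 fell when adjusted over the list alone; camera adjusted p = 0.00176, adjusted p = 0.223 with an estimated correlation). HOXB13 fell to 5.48 ± 0.455 CPM against 9.40 ± 0.616 CPM, HOXD8 to 5.60 ± 0.426 CPM against 8.88 ± 0.476 CPM, and HOXA7 had a log2 fold change of -1.38 ± 0.17. NF-kB and cytokine genes fell in 6 of 13, with LIF, TNFAIP2 and PTGS2 first, and NFKBIA rose (1 rose and 6 fell when adjusted over the list alone; camera adjusted p = 0.0185, adjusted p = 0.341 with an estimated correlation). Extracellular matrix genes rose in 21 of 28 and TGFBI fell (21 rose and 1 fell when adjusted over the list alone; camera adjusted p = 2.33e-08, adjusted p = 0.161 with an estimated correlation), with LOX, COL5A2 and TIMP3 first. Markers of the U2OS type rose in 7 of 10, with THBS1, CAV1 and CD44 first, and TGFBI fell (7 rose and 1 fell when adjusted over the list alone; camera adjusted p = 1.94e-06, adjusted p = 0.0343 with an estimated correlation). The 10 lists that missed the camera threshold were DNA replication and G1/S (14 rose, 10 fell), PI3K-PDPK1-AKT-mTOR components (11, 7), WDR5-containing complexes (10, 8), sterol and fatty acid synthesis (14, 5), immediate early genes (9, 6), YAP/TEAD targets (7, 6), interferon-stimulated genes (6, 12), heat shock (9, 3), HEK293-type markers (0, 2) and small structural RNAs (27, 12). Camera adjusted p in these lists ran from 0.0821 to 0.403. With the offset for composition and length, 7 small structural RNAs rose and 38 fell, with a median of -0.11 in place of 0.10 (camera adjusted p = 0.0570). The offset was fitted on protein-coding genes, so for these RNAs it extends a trend of other genes and settles no direction. With the offset the mitochondrially encoded list no longer passed (0.453 in place of 0.0275), and DNA replication, sterol and heat shock lists passed (0.00880, 0.00880 and 0.0146). Immediate early genes rose in 15 and translation factors in 20 with it.

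By the same rule, on CPM and overlap, increases were largest in MMP13 (log2 fold change 1.17 ± 0.10), TNFAIP6, CELF2, PIK3IP1 (0.99 ± 0.06), PMP22 (0.93 ± 0.03), FAS (0.90 ± 0.04), SMIM14 and TP53INP1. MMP13 is a collagenase, PIK3IP1 a negative regulator of PI3K, PMP22 a myelin protein and FAS a death receptor. Decreases by this rule were largest in SAMD12 (-1.32 ± 0.06), IGF2BP1 (-1.22 ± 0.08), NOTUM (-1.20 ± 0.08), LRRC49, LNX1, BATF3, TDRD7 and KCNC1. IGF2BP1 binds mRNA and NOTUM removes the lipid of Wnt proteins. All 71 named genes past the threshold stayed past it without any 1 of the 8 libraries, and counts of calls ran from 8174 to 9237. Camera's list tests rest on the preset correlation: 18 lists passed with it and 3, p53 targets, G2/M and the U2OS-type markers, with an estimated one. With fry, which makes no reference to other genes, 22 of 28 lists passed.

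Both degradations in U2OS were then set side by side. Both sets received the same compound, so changes they share cannot be told apart from an effect of dTAG47 itself. Of 17673 genes tested in both, 153 were higher in both, where independent lists would share 103 (one-sided Fisher's exact test, adjusted p = 1.92e-07 over 20 overlaps). A further 105 were lower in both, where independent lists would share 114 (Fisher's exact test, adjusted p = 1). With the offset for composition and length 231 were higher and 97 lower in both. IGFBP7, PIK3IP1, GFPT2, EMP1 and RDH10 were among those leading the genes higher in both, with log2 fold changes in the PDPK1 and WDR5 sets of 1.06 and 0.50 for IGFBP7 and 0.95 and 0.99 for PIK3IP1. RNF43 led the genes lower in both (-1.41 and -0.72), followed by ZNF480, C9orf84, CEP290, MYOCD and CASC10. For CEP290 the log2 fold change in the PDPK1 set was -0.70, and 0.02 with an offset for base composition and length. The overlap was larger among genes lower after PDPK1 and higher after WDR5 degradation, 192 against 102 from independent lists (Fisher's exact test, adjusted p = 1.72e-20). A test of the difference itself, in 1 model of all 14 U2OS libraries, called 4526 of 22864 genes. It called all 42 tested G2/M genes, with a median difference of 0.60 (WDR5 minus PDPK1 effect; camera adjusted p = 3.66e-54, adjusted p = 0.00255 with an estimated correlation). Ribosomal protein genes differed in the other direction, with 41 of 86 lower and 0 higher, or 6 higher with the offset (median -0.45; adjusted p = 2.51e-18, adjusted p = 0.234 with an estimated correlation). Without PDPK1 DMSO 2 or DMSO 3 the genes changed the same way numbered 84 or 492 in place of 258, and 141, 120 and 121 without dTAG47 1, 2 and 3.

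**Figure D2:**
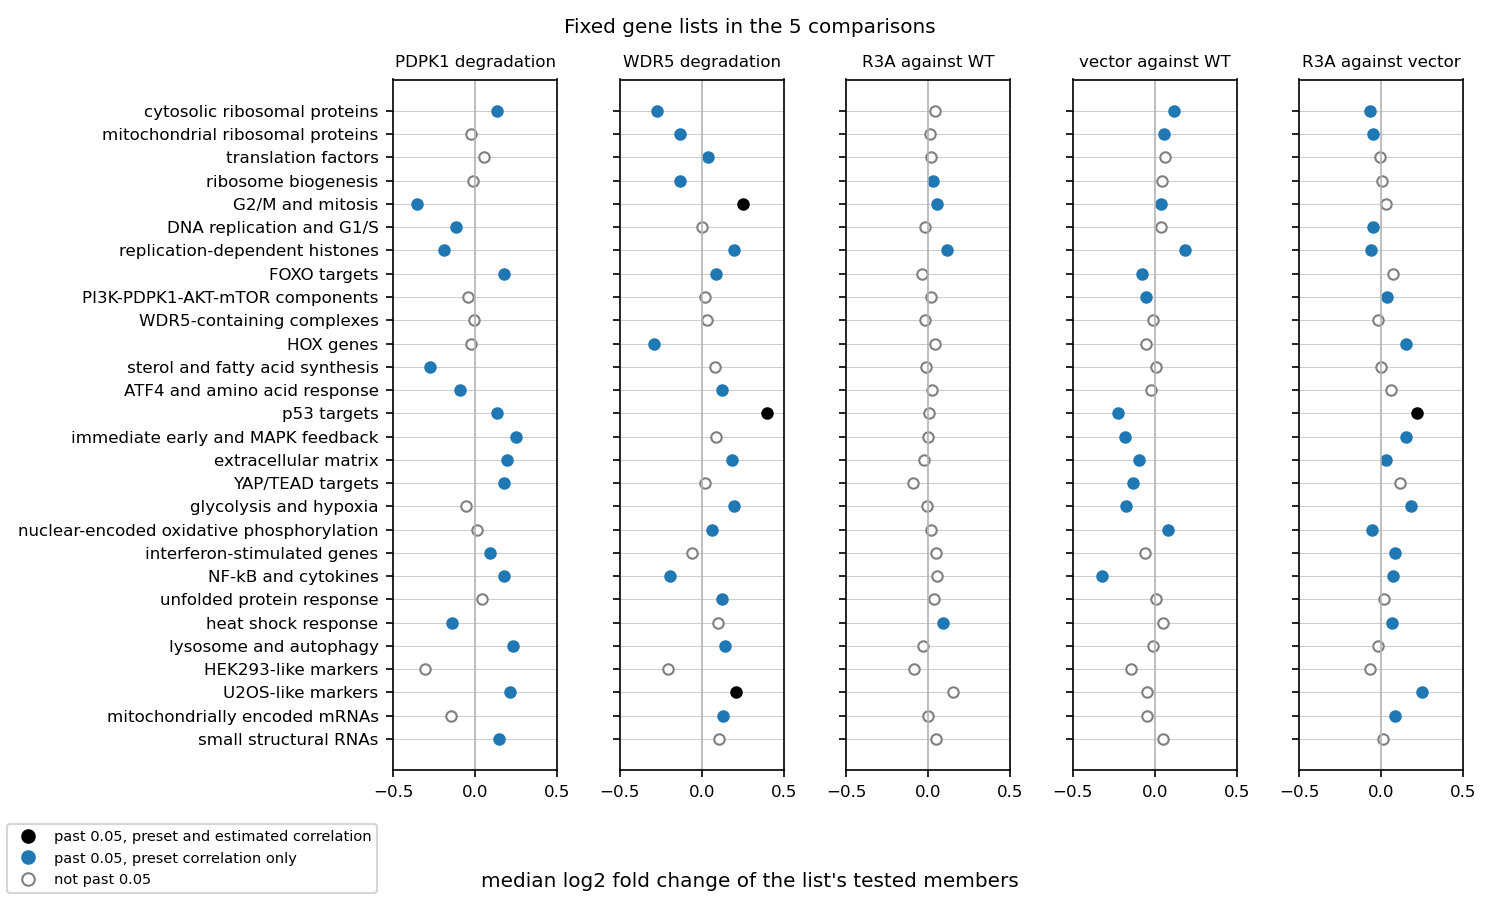
Median log2 fold change of the tested members of each of the 28 fixed gene lists (lines) in the 5 comparisons (panels). Black points passed an adjusted p of 0.05 with the preset and with an estimated correlation, blue points with the preset one alone and open circles with neither, and black points are G2/M, p53 and U2OS-type lists after WDR5 degradation and p53 targets in R3A against vector.

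The HEK293 set asked how expression in a PDPK1 R3A clone depends on wild-type PDPK1, and whether R3A PDPK1 can stand in for it. With the vector, PDPK1 and 13 of 29 p53 targets were below WT, while 24 of 54 histone and 16 of 83 cytosolic ribosomal protein genes were above it (33 of 83 with the offset for composition and length). These 3 lists passed camera's test, and none did with an estimated correlation (adjusted p = 0.163, 0.404 and 0.551 with an estimated correlation). CDKN1A fell to 54.8 ± 3.52 CPM against 92.7 ± 4.50 CPM (vector against WT, n = 2 each; log2 fold change -0.76 ± 0.06, edgeR adjusted p = 1.58e-08). HIST1H2AH, a replication-dependent histone gene, rose to 892 ± 32.3 CPM against 701 ± 72.6 CPM (0.35 ± 0.06, adjusted p = 0.000639). Of 18507 genes tested, 1073 were called, 637 higher and 436 lower, and 49 changed at least 2-fold. With upper-quartile scaling the share of higher calls was 46.9% in place of 59.4%.

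p53 targets fell in 13 of 29 and 0 rose (0 rose and 19 fell when adjusted over the list alone; camera adjusted p = 1.10e-18, adjusted p = 0.163 with an estimated correlation), with TP53INP1 at 33.9 ± 1.13 CPM against 46.6 ± 2.34 CPM and DDB2, a DNA damage sensor, at 34.3 ± 0.860 CPM against 46.8 ± 3.75 CPM. Glycolysis and hypoxia genes fell in 9 of 26 (0 rose and 14 fell when adjusted over the list alone; camera adjusted p = 6.20e-10, adjusted p = 0.437 with an estimated correlation), with LDHA, EGLN1 and NDRG1 first. Extracellular matrix genes COL6A1, COL6A2, FBLN1, TIMP3 and TNC fell, 5 of 24 (0 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.000659, adjusted p = 0.224 with an estimated correlation), COL6A1 to 15.6 ± 1.90 CPM against 24.8 ± 0.611 CPM. FOXO targets GADD45A, KLF6, SESN1 and a TXNIP entry on an alternate assembly sequence fell and RICTOR rose, of 25 (1 rose and 6 fell when adjusted over the list alone; camera adjusted p = 0.00989, adjusted p = 0.299 with an estimated correlation). ETV4, ETV5 and SPRED2 of the MAPK feedback list fell and JUN and CCND1 rose, of 27 (3 rose and 8 fell when adjusted over the list alone; camera adjusted p = 0.00336, adjusted p = 0.224 with an estimated correlation). GADD45B and TEAD1 fell among 21 YAP/TEAD targets (0 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.00684, adjusted p = 0.306 with an estimated correlation), and TNFAIP3 among 13 NF-kB genes (0 rose and 4 fell when adjusted over the list alone; camera adjusted p = 0.0170, adjusted p = 0.306 with an estimated correlation). In the PI3K-PDPK1-AKT-mTOR list PDPK1, TSC2 and RPTOR fell and RICTOR, RPS6KB1 and RPS6KB2 rose, of 30 (5 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.00417, adjusted p = 0.224 with an estimated correlation). The WT construct itself adds PDPK1 transcripts, so part of this list's shift was set by the design. The list was not tested without PDPK1.

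Replication-dependent histones rose in 24 of 54 and 0 fell (32 rose and 0 fell when adjusted over the list alone; camera adjusted p = 3.06e-11, adjusted p = 0.404 with an estimated correlation), with HIST1H2AG and HIST1H4D after HIST1H2AH. Cytosolic ribosomal protein genes rose in 16 of 83 (39 rose and 3 fell when adjusted over the list alone; camera adjusted p = 2.50e-07, adjusted p = 0.551 with an estimated correlation), with RPL7, RPL31, RPL14 and RPL8 first. Mitochondrial ribosomal proteins MRPL41, MRPL54 and MRPL27 led 5 of 74 that rose, and 1 fell (5 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.00315, adjusted p = 0.498 with an estimated correlation). Oxidative phosphorylation genes rose in 8 of 69, NDUFA5, UQCRB and UQCR10 first, and 1 fell (11 rose and 1 fell when adjusted over the list alone; camera adjusted p = 5.95e-05, adjusted p = 0.498 with an estimated correlation). G2/M genes rose in 10 of 42, with CENPF, ASPM, KIF14 and HMMR first, and KIF2C and CDC25B fell (12 rose and 4 fell when adjusted over the list alone; camera adjusted p = 0.000269, adjusted p = 0.224 with an estimated correlation). The fold changes rose with the A share of the transcript (Pearson r = 0.38, Spearman rho = 0.36, over 11437 genes). The 16 G2/M members with a high A share had a median of 0.23 and 10 calls, and the other 26 a median of -0.00 and 2 calls. Lists that missed the threshold were translation factors (4 rose, 2 fell), ribosome biogenesis (2, 0), DNA replication (2, 1), WDR5-containing complexes (0, 0), HOX (1, 2), sterol synthesis (0, 2), ATF4 (3, 2), interferon-stimulated genes (1, 0), unfolded protein response (1, 0), heat shock (2, 0), lysosome (1, 1), HEK293-type (0, 1) and U2OS-type markers (0, 1), mitochondrially encoded mRNAs (0, 1) and small structural RNAs (4, 0). With the offset 4 G2/M genes rose and 2 fell, HMMR lost its call (adjusted p = 0.838), and 8 mitochondrial ribosomal protein genes rose. Camera adjusted p was then 0.300 for G2/M, 0.0604 for FOXO, 0.0626 for MAPK feedback and 0.0792 for YAP/TEAD genes, while DNA replication (0.0213) and mitochondrially encoded mRNAs (7.27e-06, 4 fell) passed.

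Under the same rule, increases with the vector were largest in FSIP2 (log2 fold change 1.22 ± 0.18), TEX15 (1.06 ± 0.13), CENPE, CENPF (1.02 ± 0.10), EYS, CEP290, AKAP9 and GOLGA4. Decreases after PDPK1 were largest in NOTCH3 (-0.86 ± 0.14), CDKN1A, EPS8L2, FBLN1 (-0.74 ± 0.11), JUND (-0.72 ± 0.08), EEF1A2 and NEFM. NOTCH3 is a Notch receptor, FBLN1 a matrix protein and JUND a subunit of AP-1. DESeq2 called 404 genes, and CENPE and AKAP9 were not among them. Leaving out a HEK293 library leaves 1 in its group, taken to vary like the others, and calls were 507 without vector 1 and 577 without WT 1. Of 50 named genes, 20 lost their call without at least 1 library (RPL7 reached adjusted p = 0.124 and LDHA 0.0525).

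R3A PDPK1 was then compared with the vector in the same clone. The vector libraries are those of the comparison with WT, so opposite changes in both comparisons are not independent. PDPK1 and 9 of 29 p53 targets were higher with R3A. CDKN1A was at 94.1 ± 0.604 CPM against 54.8 ± 3.52 CPM (n = 2 each; log2 fold change 0.78 ± 0.06, edgeR adjusted p = 8.31e-09). ETV5, a transcription factor induced by MAPK signalling, was at 25.4 ± 0.671 CPM against 15.7 ± 1.36 CPM (0.70 ± 0.08, adjusted p = 2.25e-05). In all, 128 of 18507 genes were called, 103 higher and 25 lower. The balance moved with the fit: it was 130 higher and 99 lower with the offset for composition and length, and 169 and 72 in a fit of these groups alone.

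p53 targets rose in 9 of 29 and 0 fell (18 rose and 0 fell when adjusted over the list alone; camera adjusted p = 1.04e-26, adjusted p = 0.0408 with an estimated correlation), with DDB2 and AEN after CDKN1A. MAPK feedback genes ETV5, ETV4 and SPRED2 rose and CCND1 fell, of 27 (10 rose and 3 fell when adjusted over the list alone; camera adjusted p = 9.74e-06, adjusted p = 0.167 with an estimated correlation). COL6A1, COL6A2, TNC and TIMP1 rose among 24 extracellular matrix genes (6 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.0145, adjusted p = 0.359 with an estimated correlation). NDRG1 and PFKFB3 rose among 26 glycolysis and hypoxia genes (14 rose and 0 fell when adjusted over the list alone; camera adjusted p = 1.51e-14, adjusted p = 0.359 with an estimated correlation). PDPK1 and TSC2 rose among 30 pathway components (2 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.000651, adjusted p = 0.218 with an estimated correlation). The R3A construct itself adds PDPK1 transcripts, so part of this list's shift was set by the design. The list was not tested without PDPK1. HOXD11 rose among 37 HOX genes (1 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.00726, adjusted p = 0.410 with an estimated correlation). TNFAIP3 rose among 13 NF-kB genes (3 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.00191, adjusted p = 0.236 with an estimated correlation), and ANXA1 among 8 U2OS-type markers (2 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.00191, adjusted p = 0.236 with an estimated correlation). With 0 of their own genes called, lists of cytosolic ribosomal proteins, mitochondrial ribosomal proteins, DNA replication and histones passed the camera threshold with negative medians of -0.07, -0.05, -0.05 and -0.06 (adjusted p = 0.587, 0.452, 0.424 and 0.539 with an estimated correlation). Oxidative phosphorylation passed with a median of -0.06 and 1 gene higher (adjusted p = 0.526 with an estimated correlation). Interferon, heat shock and mitochondrially encoded lists passed with positive medians of 0.08, 0.07 and 0.08 and 0 genes called (adjusted p = 0.452, 0.359 and 0.526 with an estimated correlation). Without vector 2 the median of the mitochondrially encoded list was -0.02 (camera adjusted p = 0.209). Lists that missed it were translation factors (0 called), ribosome biogenesis (RRP12 rose), G2/M (0), FOXO targets (GADD45A rose), WDR5-containing complexes (0), sterol synthesis (0), ATF4 (SESN2 and STC2 rose, SLC7A11 fell), YAP/TEAD (GADD45B rose), unfolded protein response (0), lysosome (0), HEK293-type markers (NEFM rose) and small structural RNAs (1 rose, 1 fell). With the offset the matrix list had a median of -0.01 (camera adjusted p = 0.120), 4 mitochondrial ribosomal protein genes fell, 6 glycolysis genes rose, and small structural RNAs passed with 8 higher (0.00777). For these RNAs the offset extends a trend fitted on protein-coding genes. Oxidative phosphorylation genes then fell in 3 and rose in 0, and cytosolic ribosomal protein genes fell in 3 and rose in 1. In addition, 2 histone genes and 1 DNA replication gene fell with it.

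By that rule, increases after PDPK1 were largest in IL6R (0.80 ± 0.14), NEFM (0.78 ± 0.12), CDKN1A, EEF1A2, LAMB3, ETV5 and JUND. Decreases were largest in NOVA1 (-0.49 ± 0.11), CCND1 (-0.42 ± 0.06), SLC7A11, SCRN2, EPHA6, TMEM256, ARL16 and SERF2. CCND1 is cyclin D1 and SLC7A11 the cystine transporter. The calls numbered 48 with DESeq2, 241 in a fit of these groups alone, 36, 58 and 51 without R3A 1, R3A 2 and vector 1, and 301 and 333 without WT 1 and WT 2. Of 29 named genes, 18 lost their call without at least 1 library (DDB2 reached adjusted p = 0.0712 without R3A 2). CDKN1A, NEFM, EEF1A2, LAMB3, ETV5, JUND, IL6R and CCND1 kept theirs without each library.

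R3A against WT compares the mutant with the wild-type protein. Genes called higher with R3A had A-rich transcripts, several of them from mitotic genes. CENPF (ENSG00000117724.8, chromosome 1, 214776538 to 214837931, protein coding), a kinetochore protein, was at 574 ± 62.5 CPM against 267 ± 72.1 CPM (n = 2 each; log2 fold change 1.11 ± 0.10, edgeR adjusted p = 7.38e-07). GOLGA4, a golgin, was at 116 ± 22.5 CPM against 58.6 ± 12.9 CPM (1.02 ± 0.10, adjusted p = 1.21e-06). Calls numbered 291 of 18507, 272 higher and 19 lower, and 11 changed at least 2-fold. With the offset for composition and length, 172 were higher and 62 lower.

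G2/M genes rose in 9 of 42 and 0 fell (13 rose and 0 fell when adjusted over the list alone; camera adjusted p = 2.71e-10, adjusted p = 0.110 with an estimated correlation), with CENPF, ASPM at 399 ± 34.9 CPM against 215 ± 51.8 CPM, CENPE and KIF14 first. All 9 calls were among the 16 members with a high A share, which had a median of 0.23, and the other 26 had a median of 0.01 and 0 calls. With the offset, 5 of 42 rose (camera adjusted p = 0.00435). Among 11437 protein-coding genes above a minimum level, transcripts of those called higher had a median A share of 33.3%. The median of all 11437 was 26.4%, and log2 fold changes rose with the A share (Pearson r = 0.25, Spearman rho = 0.20). Heat shock genes HSPH1 and CHORDC1 rose, 2 of 17 (6 rose and 0 fell when adjusted over the list alone; camera adjusted p = 4.02e-05, adjusted p = 0.221 with an estimated correlation). NOP58, LYAR, RRP12 and FBL rose among 39 ribosome biogenesis genes (5 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.0123, adjusted p = 0.725 with an estimated correlation). HIST3H2BB rose among 54 histones (12 rose and 1 fell when adjusted over the list alone; camera adjusted p = 5.64e-06, adjusted p = 0.725 with an estimated correlation). The 22 histone members with a known A share and above a minimum level had a mean log2 fold change of -0.02. HSPH1 kept its call without each library, and CHORDC1 (adjusted p up to 0.664), NOP58 (0.276), LYAR (0.215), RRP12 (0.366) and HIST3H2BB (0.405) lost theirs without 2 or 3 of the 6. CHORDC1, NOP58 and LYAR also lost it with the offset, CHORDC1, LYAR and RRP12 with DESeq2, and HIST3H2BB with the replicate block and with DESeq2 size factors. p53 targets had 0 calls and a median of 0.00 (camera adjusted p = 0.746). In the other lists, none past the camera threshold, calls were EIF3E and EIF5B (higher, translation), FOXO4 (higher) and PDPK1 (lower, PI3K-PDPK1-AKT-mTOR), PMVK (higher) and FASN (lower, lipid synthesis). Further such calls were DDIT4 (higher, ATF4), JUN (higher) and MYC (lower, immediate early), FBLN1 (lower, matrix), SAMD9 (higher, interferon), ANXA1 (higher, U2OS-type), 1 oxidative phosphorylation gene (higher) and 6 small structural RNAs. Cytosolic and mitochondrial ribosomal proteins, DNA replication, FOXO targets, WDR5-containing complexes, HOX, YAP/TEAD, glycolysis, NF-kB, unfolded protein response, lysosome, HEK293-type and mitochondrially encoded lists had 0 calls. With the offset the cytosolic ribosomal protein list passed (camera adjusted p = 0.00698 in place of 0.0849).

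**Figure D3:**
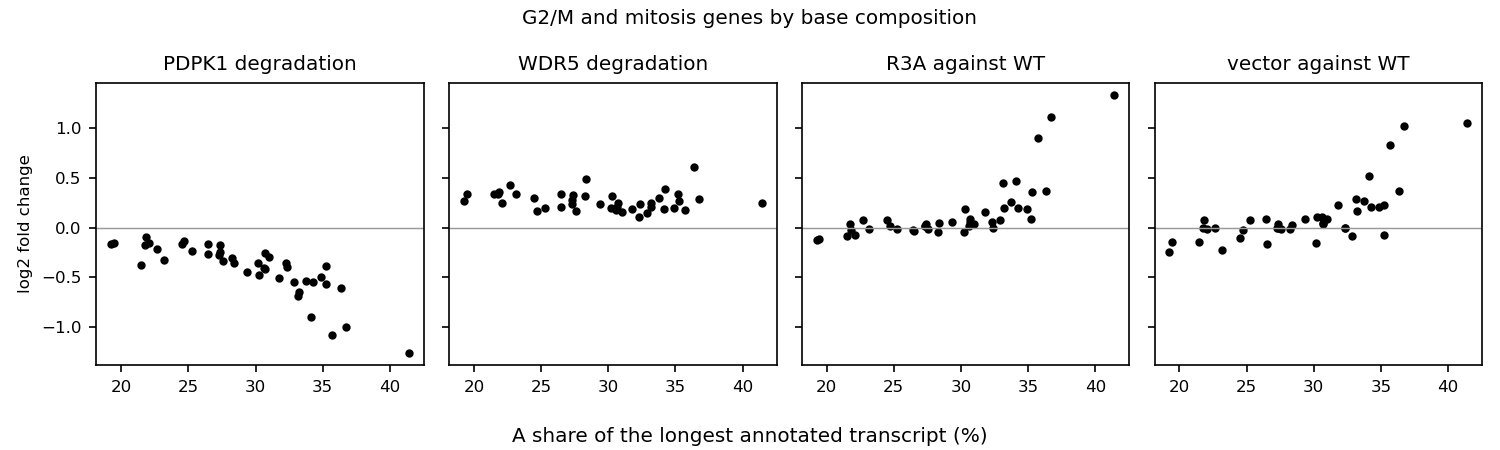
Log2 fold change of each G2/M and mitosis gene (points) against the A share of its longest annotated transcript (percent) in 4 comparisons. After PDPK1 degradation all 42 points lie below 0 and lower at high A share, after WDR5 degradation the same 42 genes lie above 0, and in both HEK293 comparisons the points above 0.5 lie at high A share.

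Beside these, and under the same rule, increases were largest in CEP290 (1.11 ± 0.11), AKAP9, GOLGB1 (0.99 ± 0.10), FAM111B and TEX15. Decreases were largest in MYC (-0.55 ± 0.11), UAP1L1, FASN (-0.49 ± 0.09), ANKRD13B, FBLN1, SEPN1, ATXN2L and DGKQ. DESeq2 called 131 genes, 130 higher and 1 lower, and neither CENPE, AKAP9, TEX15, MYC nor FASN. Counts were 143 and 176 without R3A 1 and R3A 2 and 161 and 449 without WT 1 and WT 2. Each of the 8 largest decreases lost its call without at least 1 library (MYC reached adjusted p = 0.0691 without R3A 1).

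The R3A and vector comparisons share the WT libraries. They called 229 genes higher and 11 lower in both, where independent lists would share 9.36 and 0.448. Counts of all HEK293 libraries, WT included, were simulated 30 times with no difference between groups. These simulations shared 0.7 genes on average and at most 3. They do not hold the deviations of the real WT libraries, so they cannot show how much of the overlap those give. Fold changes correlated across genes at r = 0.47, against 0.50 in the simulation. Their covariance was 0.0388 against 0.0268, a difference of 0.0120. WT was not split between the comparisons, so part of the excess may come from the shared controls. CENPF, TRIP11, ASPM, SMC3, KTN1 and ZNF480 led the shared increases and FASN, PDPK1, FBLN1, SEPN1 and AGRN were among those leading the shared decreases. The 240 shared genes numbered 129 and 156 without R3A 1 and R3A 2, and 119 and 378 without WT 1 and WT 2. With the offset 112 were higher and 31 lower in both, and with DESeq2 105 and 1.

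Between cell lines, 2 genes were higher and 0 lower both after PDPK1 degradation and in R3A against WT, of 15771 tested in both. Instead, 114 genes were lower after PDPK1 degradation and higher in R3A, where independent lists would share 7.40 (Fisher's exact test, odds ratio 35.0, adjusted p = 2.31e-107). The test takes genes as independent, while genes of a set share the trends of its libraries, so this p does not measure replication. Log2 fold changes ran with the A share in opposite directions in these comparisons (Pearson r = -0.31 and 0.25), and with the offset in both fits 43 genes were shared, with 4.61 from independent lists. Between genes lower after PDPK1 degradation and higher in vector against WT the overlap was 137, with 17.0 from independent lists, and was not repeated with the offset. WDR5 degradation and R3A against WT shared 93 genes higher in both (59.0 from independent lists, Fisher's exact test, adjusted p = 3.11e-06), led by CENPF, KIF18A, SMC3, UACA, DDIT4 and ASPM. The 3 genes lower in both, MYC, SEPN1 and ANKRD13B, compare with 3.53 from independent lists. These 96 genes were 46, 61 and 56 without R3A 1, R3A 2 and WT 1, and 54 with DESeq2. With the offset 70 were higher and 12 lower in both. The overlap was not particular to R3A. WDR5 degradation and vector against WT shared 200 genes higher (136 from independent lists, Fisher's exact test, adjusted p = 3.03e-09) and 112 lower in both (96.5). A further 152 were higher after WDR5 degradation and lower with the vector (91.3, Fisher's exact test, adjusted p = 2.18e-11), and 139 the reverse (144).

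**Figure D4:**
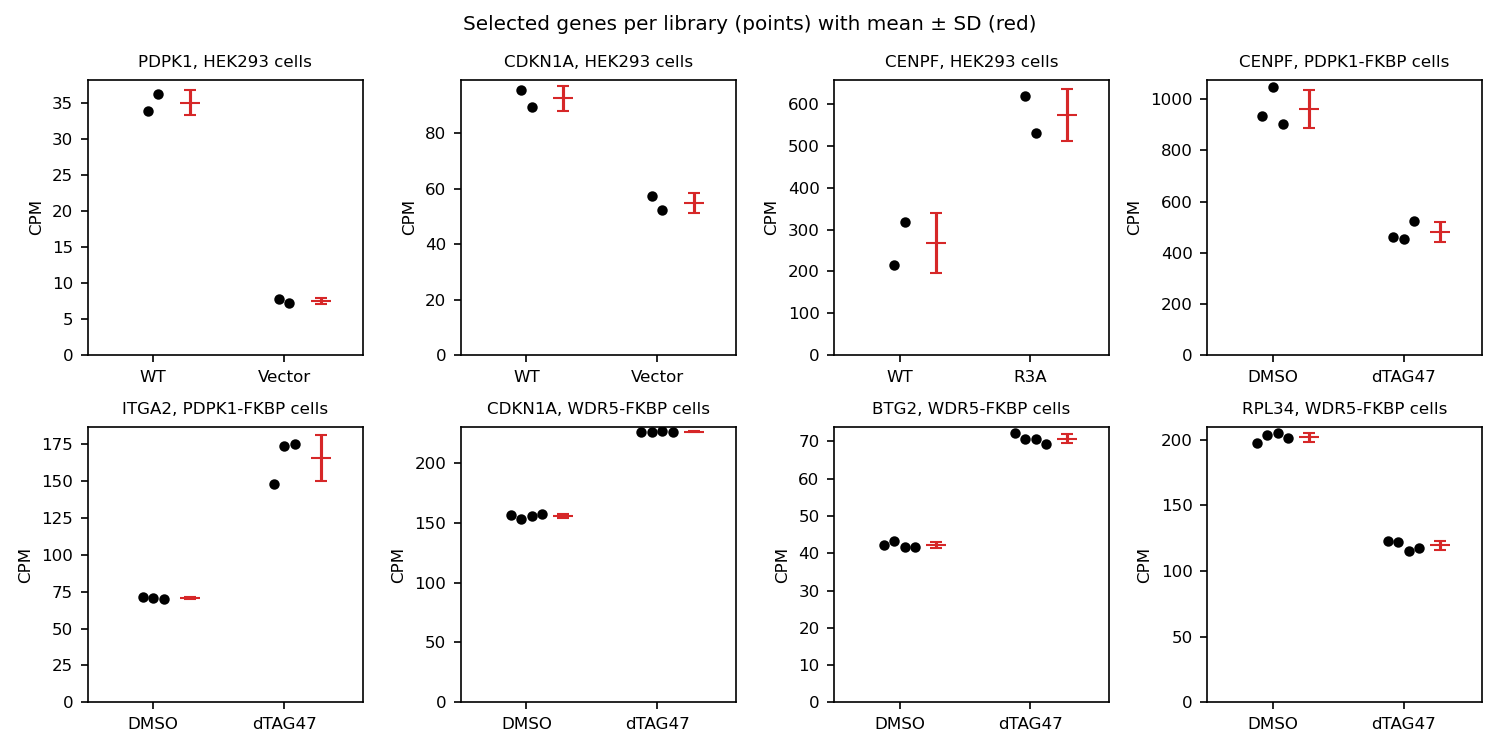
CPM per library (points) with mean ± SD (red) for PDPK1 and CDKN1A (vector and WT), CENPF (R3A and WT; PDPK1 set), ITGA2 (PDPK1 set) and CDKN1A, BTG2 and RPL34 (WDR5 set). In each panel the points of both groups do not overlap.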

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

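The tests of base composition and length and the offset for them were chosen after a trend of fold changes with A share had been seen, while the test of the difference and the splits of the libraries were planned.

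The effects of degrading WDR5 and PDPK1 differed in 4526 of 22864 genes by edgeR's test of the difference itself (4367 with DESeq2). Of 50 drawn splits of the libraries within each set, the real one included, 1 gave as many genes, and the highest other gave 1442. This argues against a random grouping of these libraries, with 1 of 50 the lowest share the splits allow. Splits cannot show whether groups also differ in culture or preparation. Of the 28 lists, 17 differed with camera at the preset correlation, 1 with an estimated correlation and 15 with fry. Each target was degraded in its own set of libraries, so the target and the set go together. The genes with the largest positive differences (WDR5 minus PDPK1 effect, log2) were the receptor gene EPHA5 (1.90), the coactivator gene PPARGC1A (1.64), CD180 (1.603), CENPE (1.47), KITLG (1.46), LPHN3 (1.40), SOX2 (1.36) and MAP1A (1.27). Those with the largest negative ones were the interferon-stimulated genes IFIT2 (-1.97) and IFIT3 (-1.96), then ACOT4 (-1.77), CATSPER1 (-1.75), RAB39B (-1.54), CHMP4C (-1.45), MAP3K7CL (-1.39) and DPY19L2 (-1.35), which has near-identical copies. All 16 kept their call without each library in turn.

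G2/M and mitosis genes had a median difference of 0.60, since they fell after PDPK1 and rose after WDR5 degradation. Their mean log2 fold change lay below all 10000 random lists matched on A share, GC share, length and expression after PDPK1 degradation (percentile 0) and above all of them after WDR5 degradation (percentile 100). The matched lists held slightly less A (28.5 against 29.3% in the PDPK1 set). With the composition offset, 23 of 42 fell (camera adjusted p = 2.14e-26; 1.32e-31 to 0.177 over all settings, the highest with an estimated correlation) and all 43 rose, which argues against composition and length as the whole cause in either set. What stays open after PDPK1 degradation is a difference in library preparation, which may account for the trend itself, since slopes on A share differed 1.66 times as much between DMSO libraries as between the group means; an effect of losing either protein on dividing cells was not tested here.

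Cytosolic ribosomal protein genes had a median difference of -0.45. Over the members used for matched lists, their mean log2 fold change was -0.21 after WDR5 and 0.14 after PDPK1 degradation. After WDR5 degradation 45 fell. With the composition offset 100% of these remained lower, which argues against composition and length as their cause. Reads shared with pseudogenes were not tested and stay open, as does an effect of WDR5 on these genes.

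p53 targets had a median difference of 0.28 (camera adjusted p = 0.0689 with an estimated correlation). For WDR5 degradation alone, 1 of 35 splits of the 8 libraries gave 9081 genes, the real one, and the highest other gave 0. This argues against a random grouping of these libraries, with 1 of 35 the lowest share the splits allow. For its lists the real split gave 18 and was 1 of 35, and the highest other split gave 16, so the count of lists alone hardly sets the real split apart. The 10 splits of the PDPK1 set are too few for a share under 0.05, with 960 genes in the real split and 2 in the highest other, and 17 lists against 15.

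In 7 of 152 groups of 4 libraries, 1 library stood apart from the other 3 by Dixon's test, which chance gives in about 1 in 20 groups. PMP22 was at 95.9 CPM in dTAG47 library 3 of the WDR5 set and at 100.5 to 101.0 in the others. HEATR1 was at 137 CPM in dTAG47 4 (133 to 134 in the others), SESN3 at 177 in dTAG47 4 (165.0 to 166) and HYOU1 at 189 in dTAG47 2 (184 to 185). In 1 DMSO library each, RPL23 was at 495 CPM (511 to 514 in the others), SESN2 at 41.6 (47.4 to 48.0) and CD44 at 137 (132 to 133).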

How the results depend on the processing

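The composition offset was added after the data were seen, and the other settings here were planned. WDR5 degradation kept 8174 to 9237 calls without single libraries and all 71 named calls without each library, with 413 genes at least 2-fold. For named genes the other settings run were DESeq2 size factors, DESeq2, limma-voom and the offset. The replicate block was added outside the WDR5 set and the difference. None of these ended a call among the 71, and a gene to which DESeq2 gave no adjusted p was passed over there. For other comparisons counts moved, and where neither fewer genes, fewer samples nor a stricter threshold shows why, the cause was not tested. Of the named calls, 25 of 56 after PDPK1 degradation, 14 of 25 in R3A against WT, 20 of 50 in vector against WT and 18 of 29 in R3A against vector were lost without at least 1 library, and 4, 15, 12 and 13 in another setting, the stricter thresholds not counted. Calls for the difference (16 named) were lost in neither. Among genes of at least 1 CPM, the simulated recovery of 1.5-fold changes was 71% in the PDPK1 set, 87% in the WDR5 set and 77 to 80% in the HEK293 comparisons. The biological coefficient of variation from edgeR was 0.102, 0.0342 and 0.0427 in these sets. Depth, number of libraries and this spread differ together between the sets, and their parts were not separated.

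Stricter thresholds gave fewer calls by construction. At an adjusted p of 0.01 they were 309 (PDPK1 degradation), 171 (R3A against WT), 412 (vector against WT), 47 (R3A against vector) and 2542 (difference). With a 2-fold minimum they were 120, 11, 49, 10 and 742. Shared genes at 0.01 were 82 (PDPK1 and WDR5 degradation), 0 (PDPK1 degradation and R3A), 53 (WDR5 degradation and R3A) and 135 (R3A and vector). With DESeq2, calls were 131 in R3A against WT, 404 in vector against WT and 48 in R3A against vector, and shared genes 1 (PDPK1 degradation and R3A), 54 (WDR5 degradation and R3A) and 106 (R3A and vector). Without a filter, calls were 1646 after PDPK1 degradation and 274 in R3A against vector. A fit of these groups alone called 241 and the offset 229 in R3A against vector. For the difference the offset gave 2601 higher and 2389 lower calls, in place of 1745 and 2781. With the offset, R3A and vector shared 143 genes, and PDPK1 degradation and R3A 1.

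Lists past the threshold fell with an estimated correlation from 17 to 0 (PDPK1 degradation), 18 to 3 (WDR5 degradation), 4 to 0 (R3A against WT), 13 to 0 (vector against WT) and 16 to 1 (R3A against vector). With fry, which asks another question, they were 10 after PDPK1 degradation, 22 after WDR5 degradation and 0, 1 and 4 in the HEK293 comparisons in that order.

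Without single libraries, calls ran from 295 (without DMSO 2) to 1848 (without DMSO 3) after PDPK1 degradation, from 143 (R3A 1) to 449 (WT 2) in R3A against WT, from 507 (vector 1) to 1092 (WT 2) in vector against WT, and from 36 (R3A 1) to 333 (WT 2) in R3A against vector. In HEK293 this leaves 1 library in a group, which is assumed to vary like the others. Shared genes ran from 84 to 492 (PDPK1 and WDR5 degradation, without DMSO 2 and DMSO 3), 0 to 3 (PDPK1 degradation and R3A, without DMSO 1 and vector 1), 46 to 143 (WDR5 degradation and R3A, without R3A 1 and WT 2) and 119 to 378 (R3A and vector, without WT 1 and WT 2). Lists in R3A against WT ran from 2 (without WT 2) to 9 (without WT 1), with 7 without R3A 1.

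Signs turned for PDPK1 and WDR5 values near 0 that passed no test, for 2 lists past their threshold and for 1 called gene. Without single libraries, log2 fold changes after PDPK1 degradation ran from -0.103 (without DMSO 1) to 0.0458 (DMSO 3) for PDPK1 and from -0.0339 (dTAG47 3) to 0.0352 (DMSO 3) for WDR5, which was at 0.00490 with DESeq2. In R3A against vector they ran from -0.0978 to 0.0210 for WDR5 and, for the median of the mitochondrially encoded list, from 0.187 to -0.0244 (without vector 1 and vector 2; adjusted p = 0.209 in the latter). With the offset the extracellular matrix list in R3A against vector moved from 0.03 to -0.01, and small structural RNAs, past no threshold, from 0.10 to -0.11 after WDR5 degradation and from 0.05 to -0.05 in vector against WT. The offset was fitted on protein-coding genes, so for structural RNA it extends a trend of other genes and settles no direction. In the difference PDPK1 ran from 0.134 to -0.00714 (without PDPK1 DMSO 1 and 3), and WDR5 was at 0.0674 with the offset. CEP290 after PDPK1 degradation moved from -0.70 to 0.0246 with the offset, which by construction removes the fitted trend with composition and length.

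The replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at 0.14, -0.04 and -0.08 in the PDPK1 set, where only number 1 matched its own number best, and at -0.03, -0.07 and -0.01 in HEK293. With the number as a replicate block, calls were 924 after PDPK1 degradation, 303 in R3A against WT, 993 in vector against WT and 153 in R3A against vector. Shared genes were 2 (PDPK1 degradation and R3A) and 249 (R3A and vector), and lists 17, 4, 13 and 16, each within 1.5 times the unblocked count. The block was planned but not run for WDR5 degradation, the difference and the overlaps with WDR5 degradation. Read without punctuation, the names of the DMSO columns of the WDR5 table, except DMSO 4, match labels in both U2OS sets. As written they match the WDR5 set alone, but their numbers were not used.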

Other observations

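The offset for composition and the matched lists were chosen after the trend with A share had been seen, and the levels below are from the planned fits.

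In HEK293, 13 of 29 p53 targets were lower with the vector than with WT (list adjusted p = 0.163 with an estimated correlation), and 9 of 29 were higher with R3A than with the vector (0.0408). Their mean log2 fold change was -0.28 in vector against WT, below all lists matched on composition, length and expression, and 0.27 in R3A against vector, above all of them. Both comparisons use the same vector libraries, so these values are not independent of each other. The matched lists take no account of members that vary together. In R3A against WT it was -0.01, at percentile 16.1 of the matched lists. CDKN1A, the p21 gene, was at 94.1 CPM with R3A and 92.7 CPM with WT against 54.8 CPM with the vector, and its log2 fold change between R3A and WT was 0.02 ± 0.06. After WDR5 degradation in U2OS the mean of the same list was 0.42, and after PDPK1 degradation 0.10.

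One hypothesis is that the mitotic genes higher in R3A and vector libraries reflect the composition and length of their transcripts. In vector against WT the list lay at percentile 93.6 of the matched lists, and with the offset 4 genes rose and 2 fell, so composition and length remain a candidate explanation there. In R3A against WT it lay at percentile 99.96, and 5 genes rose with the offset (camera adjusted p = 0.00435, 2.71e-12 to 0.110 over all settings). This argues against composition and length as the whole cause only as far as matching and offset capture them. The matched lists held less A (28.5 against 29.3%). Within the list, log2 fold changes rose with A share (Spearman rho = 0.83), and members without a high A share had a median of 0.01. Slopes on A share differed 1.205 times as much within a group as between the R3A and WT means, so library preparation may account for the trend in R3A against WT. For vector against WT the ratio was 0.584, so slopes differed less within a group than between the means. No prediction was set for this comparison, and library preparation stays open there. An effect of the R3A protein on mitotic genes was not tested apart from this and stays open.

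A second hypothesis is that the genes lower after PDPK1 degradation and higher in R3A are joined by composition and length alone. With the offset in both fits the shared genes fell from 114 to 43, against 4.61 from independent lists. The remaining overlap argues against composition and length, as far as the offset removes them, as the whole cause, and the drop may reflect their part in it.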
